A study of Mus musculus with 6 samples.

How the data were processed

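Gene expression was measured by RNA sequencing in Lewis lung carcinoma (LLC) cells, a mouse lung cancer line. Per the labels, cells received Cas9 with a guide RNA against calreticulin or with a control guide, were cultured for 10 days, and were then seeded in 3 wells per group and collected 48 hours later with a phenol-based reagent. Libraries were made from total RNA with a SMARTer mRNA-seq kit, and all 6 libraries carry the same batch label. The groups are Calr KO (n = 3) and control (n = 3). The design text describes 1 population of cells per group divided over 3 wells, so no p-value here measures the spread between independent knockouts. The p-values of single genes measure the spread between wells. Tests that compare the genes of a list with other genes rest on the spread between genes. Their small p-values are not evidence over replicate wells.

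The deposited table holds a signal per gene and library, which are gene counts normalised by the authors with DESeq2, per the labels. The submitters' processing notes name STAR 2.6.1d, Salmon 0.14.1, DESeq2 1.34.0 and the mm10 build, without their roles or order. The annotation release is not given in the sources used here. The table has 55291 gene symbols, of which 23156 were above 0 in at least 1 library. The 6 columns sum to between 14040693 and 14099985 normalised counts. The most frequent value within a low range above 0 in each library was taken as the worth of 1 read. It lay between 0.945 and 1.04, which gives an estimated 13571210 to 14918661 reads per library. Between 79.3% and 82.9% of the values under 1.5 reads were whole multiples of it within 0.02, and between 3.44% and 4.31% of the values of 100 to 1000 reads were. Whole reads could therefore not be recovered, and no count model was run. Counting intervals cover counting error only, since reads carried no molecular identifiers that are used here.

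Genes with a mean of at least 10 normalised counts over the 6 libraries were tested, 13199 in all. Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a variance prior that follows the mean, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Every adjusted p for a gene is from this limma test unless another is named. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Means are given ± SD over n = 3 libraries.

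The genes named were set by a rule before the data were examined. Calr came first, then up to 10 genes that rose and 10 that fell with an adjusted p under 0.05, a log2 change of at least 1 in size, a mean of at least 50 and no overlap between the groups, without unnamed gene models. Then came up to 4 members of each fixed list with the smallest adjusted p, or up to 2 of the highest mean where no member passed, and any other member with its value. The rule took 2 genes that rose and 0 that fell. Genes outside it are named as chosen after their values were seen. The values of some single genes are not reported here.

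The 27 fixed lists cover ER chaperones and co-chaperones, protein disulfide isomerases and oxidases, ER-associated degradation, sensors and transducers of the unfolded protein response (UPR), the PERK-ATF4-CHOP stress response, amino acid synthesis and transport, cytosolic tRNA synthetases, N-glycosylation and the calnexin cycle, ER translocation and early secretory traffic, and ER calcium handling. They also cover MHC class I antigen presentation, the interferon response, chemokines and cytokines, immune ligands and phagocytosis signals, NF-kB targets, p53 targets, apoptosis regulators, the cell cycle, extracellular matrix and collagen processing, integrins and adhesion, and epithelial-mesenchymal markers. The remaining lists hold targets of SREBP, the NRF2 antioxidant response, the cytosolic heat shock response, hypoxia and glycolysis, calcineurin-NFAT and calcium-responsive genes, and mitochondrially encoded transcripts. Calr is in no list. Lists were tested with limma's camera, which compares a list with all other tested genes, at a preset correlation of 0.01 and again with an estimated correlation. The fry test, which asks whether a list's genes move one way without comparing them with other genes, was run beside it. Each was adjusted over the 27 lists. Differences between 2 lists were tested over libraries with a two-sided exact permutation test, and over genes with camera, each adjusted over the pairs tested. A further 5 lists held markers of macrophages, lymphocytes, endothelium, fibroblasts and lung epithelium.

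Alternatives fixed before the data were examined were other pseudocounts, filters on low values, scalings and variance priors, voom weights, the replicate number as a block, and leaving out each library in turn. A correction for GC content and transcript length was chosen after seeing the data and used 98.3% of the tested genes. Gene coordinates are from GENCODE M21 on GRCm38, the assembly that mm10 names. The procedure was tested on simulated data for this comparison with 13057 genes. It recovered 30.0% of genes changed 1.2-fold, 59.2% at 1.5-fold, 89.8% at 2-fold and 95.7% at 4-fold, and 2.92% of its calls were false. With no gene changed it called 0 of 13066. In the simulation the spread of a gene depended on its mean alone and genes were drawn independently. That is what the variance prior assumes, so these shares need not hold for the real data. Figures were drawn with matplotlib 3.10.9.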

Results

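RNA was sequenced from LLC cells, a mouse lung carcinoma line, after targeting of Calr, which encodes the calcium-binding ER chaperone calreticulin, and from cells that received a control guide. There were 3 Calr KO and 3 control libraries, each summing to between 14040693 and 14099985 normalised counts. The comparison addresses the ER stress response named in the title of the series. Correlations of log2 values over genes were 0.985 to 0.986 between libraries of 1 group and 0.984 to 0.986 between groups.

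Calr mRNA was lower in all 3 Calr KO libraries than in all 3 controls. The gene (ENSMUSG00000003814.8, protein coding, minus strand of chromosome 8, positions 84841850 to 84846934 on GRCm38) had 4379 ± 141 normalised counts in Calr KO and 10653 ± 426 in control cells (SD, n = 3). The Calr KO libraries held 4467, 4216 and 4453 and the controls 10711, 10202 and 11047. The change was -1.28 on the log2 scale (SE 0.04, limma adjusted p = 7.9e-07), 2.43-fold lower. Transcript remained in every Calr KO library, and mRNA level measures neither the edited alleles nor the protein. Among related genes, Calr3 had 48.1 ± 3.40 against 62.5 ± 12.3 and did not pass the test, and the pseudogene Calr-ps was listed at 0 in all libraries.

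Calr KO cells differed from control cells in 37 genes, of which 26 were higher and 11, Calr included, were lower. Among the higher genes were the ER folding factors Pdia6, Pdia4, Hsp90b1, Pdia3 and Sdf2l1. Most changes were small, and 5 genes changed at least 2-fold. These were Calr on the lower side and Lama3, Zfp738, Plce1 and Fstl5 on the higher side. In all 37 genes the groups did not overlap, as in 14.8% of all tested genes against 10% by chance. An unadjusted p under 0.05 was found for 1172 of 13199 genes, with 660 expected by chance. With a single variance prior for low and high genes instead of one that follows the mean, 2 genes passed, Calr and Lama3. Leaving out Calr KO replicate 1 gave 20 genes, Calr KO replicate 3 gave 21, and control replicates 2 and 3 gave 22 each; the count of at least 2-fold was 3 without Calr KO replicate 1 or 2 or control replicate 3. In all, 17 of the 37 passed without each library in turn.

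**Figure D1:**
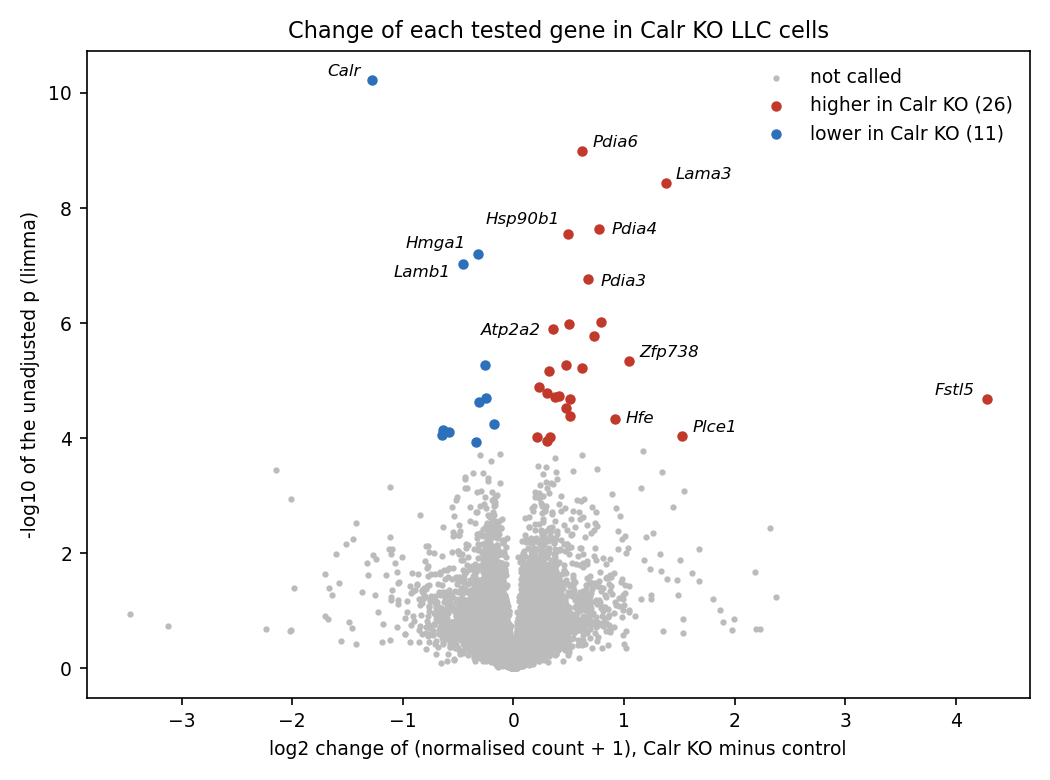
Change of each of 13199 tested genes, with the log2 change of (normalised count + 1) on the x axis, Calr KO minus control, and -log10 of the unadjusted limma p on the y axis. Red points are the 26 genes that were higher at an adjusted p under 0.05, blue points the 11 that were lower, and grey points all others; Calr lies alone at the upper left, at -1.28.

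Of 20 measured ER chaperones and co-chaperones, 11 rose in Calr KO cells, 0 fell and 9 did not pass over all genes tested, and 12 rose adjusted over the list alone. Hspa5, the BiP chaperone that binds the stress sensors, rose 1.42-fold from 20765 ± 971 to 29459 ± 1697. Hsp90b1, the ER member of the HSP90 family, rose 1.41-fold from 30390 ± 736 to 42848 ± 1600. The BiP-associated factor Sdf2l1 rose 1.73-fold (1753 ± 103 against 1011 ± 80.8) and the secreted Creld2 rose 1.66-fold. Dnajc3, Hyou1, Dnajb11, Manf, Canx, Ppib and Serpinh1 rose by 0.62, 0.47, 0.52, 0.51, 0.30, 0.30 and 0.23 on the log2 scale. The list's median change was 0.29 (limma camera adjusted p = 4.4e-23, and adjusted p = 0.081 with an estimated correlation). Without Calr KO replicate 1, Calr KO replicate 3 or control replicate 2 the count was 6, without control replicate 3 it was 7, and with a single variance prior it was 0. Canx, the membrane-bound homologue of calreticulin, lost its call in 5 of the 6 fits, with a highest adjusted p of 0.14 without Calr KO replicate 1. Dnajb11, Manf, Ppib and Serpinh1 lost theirs in 4 fits each, with a highest adjusted p of 0.0958, for Manf without Calr KO replicate 1.

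Of 17 measured protein disulfide isomerases and oxidases, which form and rearrange disulfide bonds in the ER, 3 rose and 0 fell. Pdia4 rose 1.71-fold (8470 ± 520 against 4946 ± 104), Pdia3, the partner of calreticulin and calnexin, 1.60-fold (16149 ± 999 against 10104 ± 505) and Pdia6 1.53-fold (27472 ± 607 against 17903 ± 403). These 3 passed without each library in turn. Adjusted over the list alone, 6 rose and 1 fell. The added genes were Erp44, Ero1lb and Erp29, with log2 changes of 0.38, 0.41 and 0.30, and Ero1l at -0.20. P4hb, the classical protein disulfide isomerase, changed by 0.10 (adjusted p = 0.505). The list had a median of 0.10 and a camera adjusted p of 6.1e-08, with an adjusted p = 0.275 with an estimated correlation.

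**Figure D2:**
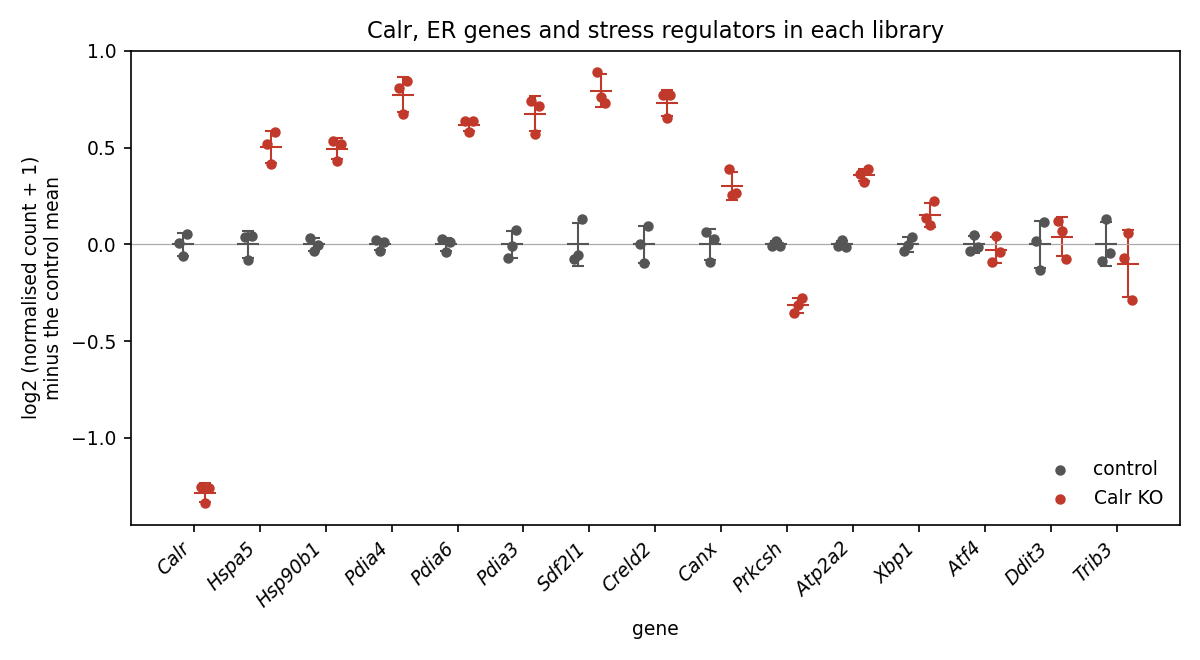
Values of 15 genes in each library, as log2 (normalised count + 1) minus the control mean, with points for single libraries and bars for the mean ± SD (n = 3 per group). Calr lies at -1.28 and the 7 chaperones and disulfide isomerases from Hspa5 to Creld2 lie at 0.50 to 0.79 in Calr KO, whereas Atf4 and Ddit3 overlap with control.

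N-glycan processing genes moved in both directions. Of 21 measured members of N-glycosylation and the calnexin cycle, Rpn1 and Magt1, subunits of oligosaccharyltransferase, rose by 0.41 and 0.33, and Canx rose as given above. Prkcsh, the regulatory subunit of glucosidase II, fell by 0.32 (2090 ± 56.0 against 2600 ± 27.6, adjusted p = 0.013), whereas its catalytic partner Ganab changed by -0.03 (adjusted p = 0.873) and Uggt1 by 0.05 (adjusted p = 0.677). Adjusted over the list alone, 4 rose, with Lman1 at 0.19, and 1 fell. The median was 0.06 (camera adjusted p = 0.0017, and adjusted p = 0.281 with an estimated correlation). The call of Prkcsh was lost without Calr KO replicate 1, Calr KO replicate 2, control replicate 2 or control replicate 3, with a highest adjusted p of 0.0800. Magt1 lost its call without any 1 of the 6 libraries, with a highest adjusted p of 0.178, and Rpn1 without Calr KO replicate 1 (0.0654) or 3.

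In ER-associated degradation, early secretory traffic and ER calcium handling, 1 gene passed over all genes tested, Atp2a2. Of 22 measured genes of ER-associated degradation none passed over all genes tested, while 3 rose adjusted over the list alone, Sel1l (0.34), Syvn1 (0.26) and Edem1 (0.25). The median was 0.04 (camera adjusted p = 0.014, and adjusted p = 0.275 with an estimated correlation), and the camera adjusted p was 0.051 without Calr KO replicate 3. Of 28 genes of translocation and early secretory traffic 0 passed over all genes and 6 rose adjusted over the list alone, among them Tmed2 (0.38), Spcs2 (0.32) and Sec11c (0.46); without control replicate 1, or with a mean of at least 1 or no filter on low values, 1 member passed over all genes, Tmed2 (adjusted p = 0.0091 without that library). Their median was 0.06 (camera adjusted p = 0.0027, and adjusted p = 0.434 with an estimated correlation), with a camera adjusted p of 0.070 without control replicate 2. Among 21 ER calcium genes, Atp2a2, the SERCA pump that fills the ER with calcium, rose 1.28-fold (5510 ± 123 against 4296 ± 57.9, adjusted p = 0.0015), and adjusted over the list alone 2 rose, with the plasma membrane pump Atp2b1 at 0.20. Calu, the most abundant member, changed by -0.01. The calcium list had a median of 0.06 (camera adjusted p = 0.036, and adjusted p = 0.276 with an estimated correlation); the camera adjusted p was 0.201 without Calr KO replicate 1, 0.071 without control replicate 1 and 0.080 without control replicate 2.

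The genes that sense ER stress did not pass. Among 14 measured UPR sensors and transducers 0 passed over all genes or adjusted over the list alone. Xbp1 changed by 0.15 (adjusted p = 0.454), Ern1 by 0.13, Eif2ak3 by 0.11, Atf6 by -0.13 (adjusted p = 0.307) and Eif2s1 by 0.02. The median was 0.07 (camera adjusted p = 0.225, and adjusted p = 0.434 with an estimated correlation), and the camera adjusted p was 0.031 without Calr KO replicate 2. The values are gene totals, so the spliced form of Xbp1 was not measured. The mRNA levels also do not measure the activity of the sensors.

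The PERK-ATF4-CHOP arm, which couples ER stress to translation control and cell death, showed no call in its 18 measured genes, either over all genes or adjusted over the list alone. Atf4 had 11142 ± 513 normalised counts in Calr KO and 11368 ± 348 in control (log2 change -0.03, 95% interval -0.11 to 0.06). The ATF4 protein was not measured. Ddit3, which encodes CHOP, changed by 0.04 (95% interval -0.17 to 0.24) and Trib3 by -0.10 (95% interval -0.32 to 0.12). The list's median was -0.02 (camera adjusted p = 0.439, and adjusted p = 0.750 with an estimated correlation). Without Calr KO replicate 2 the median was -0.09 with a camera adjusted p of 0.018, and it was above 0 without Calr KO replicate 3 (0.02) or control replicate 2 (0.01). The 20 genes of amino acid synthesis and transport, many of them ATF4 targets, had a median of -0.06 (camera adjusted p = 0.026, and adjusted p = 0.595 with an estimated correlation) with 0 passing over all genes or adjusted over the list alone; Psat1 changed by -0.09, Asns by -0.06. That camera adjusted p was 0.324 without Calr KO replicate 1, 0.174 without Calr KO replicate 3 and 0.252 without control replicate 2.

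In each library the mean log2 value of the ER chaperones was set against that of another list. The difference was higher in all 3 Calr KO libraries than in all 3 controls for each of 4 lists, by 0.33 against the PERK-ATF4-CHOP genes (SD 0.13 in Calr KO and 0.14 in control, n = 3), 0.36 against the amino acid genes (SD 0.10 and 0.09), 0.34 against the cytosolic heat shock genes (SD 0.04 and 0.03) and 0.24 against ER-associated degradation (SD 0.04 and 0.04). A two-sided exact permutation test gave p = 0.1 for each, also after adjustment over the 4. That is the smallest this test allows with 3 libraries against 3, so it could not reach the threshold. Camera on the lists of each pair, which compares genes, gave adjusted p values of at most 5.3e-04 at the preset correlation. With an estimated correlation its adjusted p was 0.032 for the PERK-ATF4-CHOP genes and 0.031 for the amino acid genes. It was 0.032 for the heat shock genes and 0.059 for ER-associated degradation. In each pair camera used the correlation of the chaperone list, 0.13, and took the genes of the other list as independent. The correlations estimated for the PERK-ATF4-CHOP and amino acid lists were 0.27 and 0.40. The camera p-values of these pairs are therefore likely too small. Of 12 measured cytosolic heat shock genes 1 fell, also adjusted over the list alone, Hspa4l by 0.26. The abundant Hsp90ab1 and Hspa8 changed by -0.02 and 0.0048, and the sign of the latter depends on the scaling; the list had a median of -0.00025 (camera adjusted p = 0.531). These 4 pairs were chosen after the list results were seen.

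**Figure D3:**
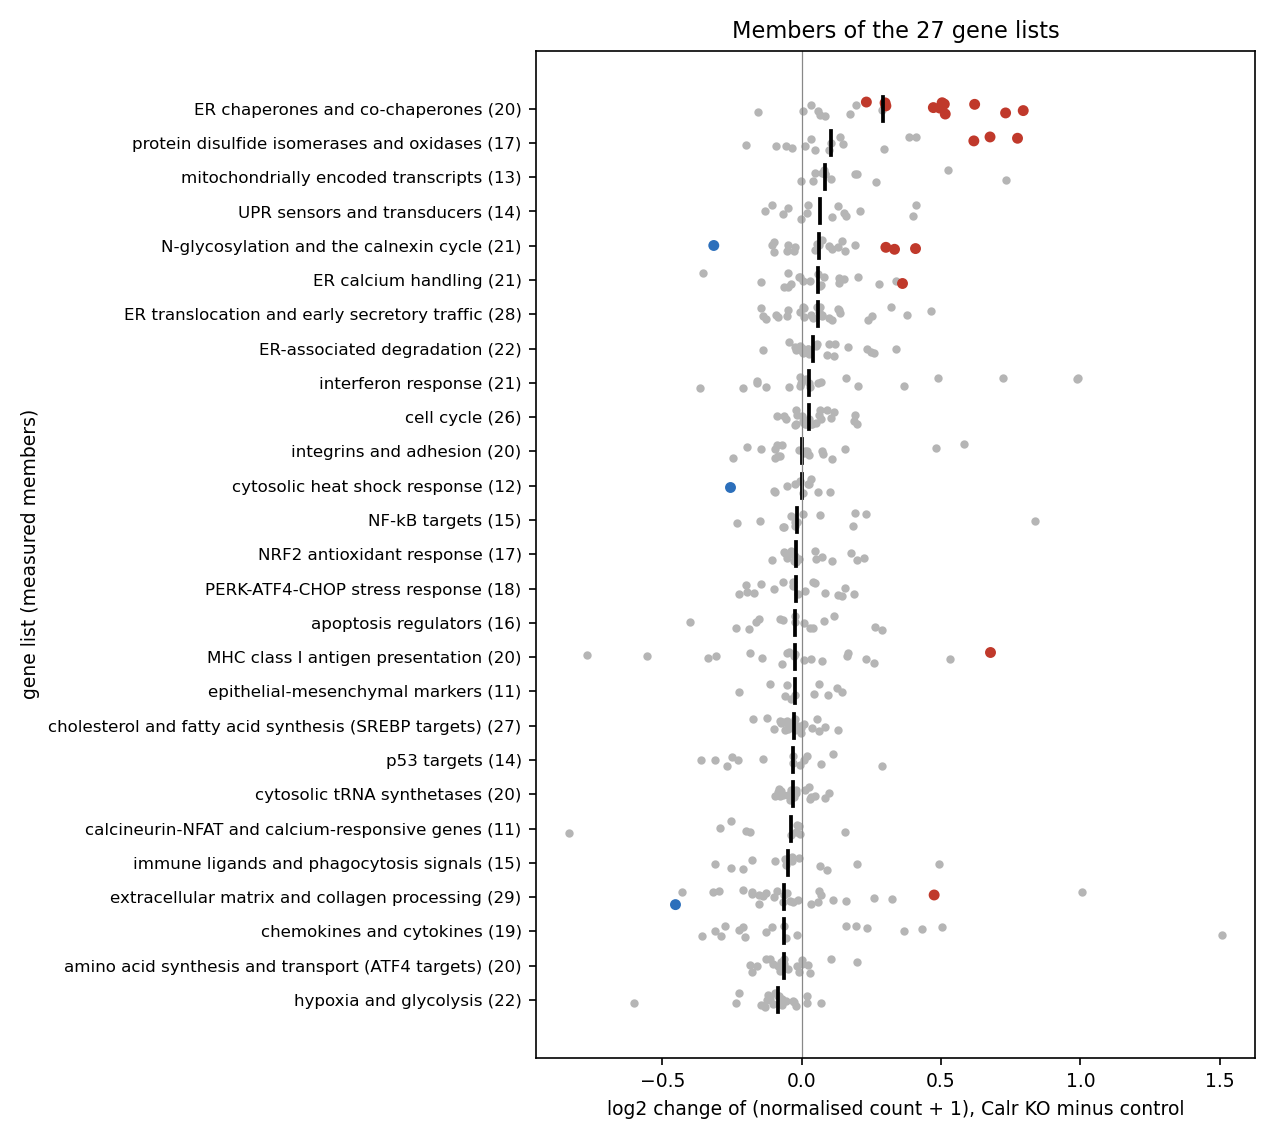
Members of the 27 fixed lists, with the log2 change of (normalised count + 1) on the x axis, Calr KO minus control. Each point is a measured gene, red where it was higher and blue where it was lower at an adjusted p under 0.05, grey otherwise, and the black bar is the list's median, which is 0.29 for the ER chaperones.

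Of the 26 genes that were higher, 17 belong to the union of the 7 ER lists, against 0.28 expected from its 142 tested genes among 13198 (Fisher's exact test, two-sided, p = 3.7e-28). Of the 10 lower genes other than Calr, Prkcsh belongs to it (Fisher's exact test p = 0.103). The union was formed after the data were seen, and genes are not independent replicates. The expected number also takes all tested genes as equally likely to be called. Low genes had larger errors, for example an SE of 0.23 for Plce1 against 0.025 for the abundant Pdia6. The mitochondrial share of the counts, a sign of RNA quality and cell state, was 2.82%, 2.85% and 2.91% in the Calr KO libraries that held the raised ER genes and 2.75%, 2.73% and 2.72% in the controls.

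Outside the ER, Lama3 and Zfp738 were the genes taken by the size rule. Lama3, a laminin alpha chain of epithelial basement membranes, rose 2.59-fold (1487 ± 42.0 against 573 ± 37.8, adjusted p = 1.6e-05; chromosome 18, positions 12333819 to 12583013). Zfp738, a zinc finger gene of a large family in which reads can be shared, rose 2.06-fold (516 ± 5.78 against 252 ± 37.8, adjusted p = 0.0047). Both passed without each library in turn. The following genes were chosen after their values were seen. Plce1, a phospholipase C, rose 2.87-fold from a low level (53.3 ± 6.85 against 17.9 ± 2.19, adjusted p = 0.036), but its call was lost without any 1 of the 6 libraries (highest adjusted p 0.182). Fstl5 had an estimated 72 reads in the 3 Calr KO libraries and 1 in the 3 controls, a ratio of 72.2 (95% exact counting interval 12.5 to 2889, limma adjusted p = 0.012), but its adjusted p was 0.089 without Calr KO replicate 2, and without Calr KO replicate 1 or 3 its mean fell under 10 and it was not tested. Among lower genes, Lamb1, the laminin beta chain, fell by 0.45 (8039 ± 244 against 10999 ± 188) and the chromatin protein gene Hmga1 by 0.32. Hmga1b, a near-identical copy of Hmga1, fell by 0.34, and reads of the pair can be shared, so their separate values are uncertain; the call of Hmga1b was lost in 5 of the 6 fits with a library left out (highest adjusted p 0.161, without Calr KO replicate 1).

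Calreticulin assists the loading of MHC class I molecules and at the cell surface serves as a phagocytosis signal. Of 20 measured MHC class I presentation genes 1 rose, Pdia3, which is also in the disulfide isomerase list, and adjusted over the list alone H2-T23 also passed, at -0.55. H2-K1 changed by -0.19 (adjusted p = 0.381), H2-D1 by -0.07, B2m by 0.03 and Tap1 by -0.05, and reads of the related H2 genes can be shared. The median was -0.02 (camera adjusted p = 0.905). Of 15 measured immune ligands and phagocytosis signals 0 passed over all genes; adjusted over the list alone 2 rose, Raet1d (0.49) and Hmgb1 (0.09), and 2 fell, Lrp1 (-0.25) and Pvr (-0.18). Without Calr KO replicate 1, Lrp1 passed over all genes (-0.35, adjusted p = 0.037). Cd47 changed by -0.06 and Cd274 by -0.21 (adjusted p = 0.773), and the camera adjusted p was 0.583. In 21 measured interferon response genes 0 passed over all genes or adjusted over the list alone, with Bst2 at 0.16 (adjusted p = 0.541) and a camera adjusted p of 0.274.

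Mitochondrially encoded transcripts had a median change of 0.08, with 0 of 13 passing over all genes and 8 rising adjusted over the list alone, among them mt-Atp8 (0.27), mt-Cytb (0.11), mt-Nd3 (0.73) and mt-Co1 (0.04). The camera adjusted p was 6.4e-09, and adjusted p = 0.081 with an estimated correlation. Hypoxia and glycolysis genes had a median of -0.08, with 0 of 22 passing over all genes and 5 falling adjusted over the list alone, among them Pgk1 (-0.12, which passed over all genes after the GC content and length correction, adjusted p = 0.0497), Aldoa (-0.09) and Vegfa (-0.22). Their camera adjusted p was 1.8e-07, and adjusted p = 0.283 with an estimated correlation. Over the 27 lists, camera called 9 at the preset correlation, 7 up and 2 down, and 0 with an estimated correlation, while fry called 7, 5 up and 2 down. By fry the ER chaperones (adjusted p = 0.010), disulfide isomerases (0.014), ER-associated degradation (0.014), ER calcium (0.034) and mitochondrial lists (0.014) moved up, and the extracellular matrix (0.014) and p53 lists (0.037) moved down.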

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

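The correction for GC content and length was chosen after seeing the data; the other settings were planned. Over 19 alternative settings Calr and Lama3 stayed past the threshold, and 15 further genes lost it only without the variance trend. No called gene changed sign in any of these settings. Without the trend 2 genes passed, both at least 2-fold; that setting gives low and high genes 1 prior variance. Leaving out 1 library gave 20 to 34 genes (20 and 25 without Calr KO replicates 1 and 2, 21 without replicate 3, 34, 22 and 22 without control replicates 1, 2 and 3) and 3 to 5 genes of at least 2-fold, with fewer samples in each fit. The 2-fold count was 3 with a mean of at least 50, which removes Plce1 and Fstl5, and 3 with the replicate block. The replicate numbers do not pair the libraries: same-numbered libraries had deviations correlated at -0.056, -0.011 and 0.001, and no library correlated best with its own number. With the replicate block 26 genes passed, 21 higher and 5 lower, all among the 37. The remaining settings gave 35 to 42 genes. No list was called by camera with an estimated correlation (0 of 27), against 9 at the preset one and 7 by fry. With a library left out camera called 6 to 13 lists, 13 without Calr KO replicate 2, where the UPR sensor, PERK-ATF4-CHOP, cell cycle and SREBP lists were added. The calcineurin-NFAT list was called with a mean of at least 1 (adjusted p = 0.036), with the replicate block (0.041) and without Calr KO replicate 3 (0.031). Without the trend the amino acid (0.108) and ER calcium (0.081) lists were not called. With libraries left out in turn, list medians ranged from 0.019 to 0.10 for UPR sensors (past the threshold without Calr KO replicate 2, adjusted p = 0.031), from 0.021 to 0.064 for ER-associated degradation (adjusted p = 0.051 without Calr KO replicate 3) and from -0.088 to 0.022 for the PERK-ATF4-CHOP genes, whose median changed sign without Calr KO replicate 3 or control replicate 2. The cause was not tested. Genes that were not called also changed sign with a library left out. Lamb2, at -0.21, ranged from -0.33 to 0.018 and was above 0 only without control replicate 2. The others, at -0.05 (Tap1) to 0.10 (Egfl7), had log2 ranges of -0.065 to 0.00039 for Atf4, -0.026 to 0.097 for Ddit3, -0.094 to 0.021 for Tap1, -0.074 to 0.10 for Pdgfra, -0.053 to 0.042 for Ccl2, -0.031 to 0.11 for Cd14, -0.011 to 0.16 for Egfl7, -0.0083 to 0.025 for Hspa8, -0.26 to 0.23 for Kdm5d, -0.056 to 0.0074 for Lamc1 and -0.035 to 0.033 for Mef2d. Under other scalings Hspa8 was -0.085 by quantile normalisation and -0.0059 by upper quartile, and Hsp90ab1 was 5.6e-15, a numerical 0, by quantile normalisation. Mef2d was 0.015 after the GC content and length correction. The count-model tests planned for whole reads were not run, since whole reads could not be recovered. Depth limits low genes such as Fstl5 and Plce1, and changes near 1.2-fold were mostly missed in simulated data.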

Other observations

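The tests of other splits of the libraries and of another difference between the pools, the setting with the GC content and length correction, and the bound on the mean of the Y genes were chosen after the results were seen. Laminin chains moved in opposite directions in Calr KO cells. Lama3 rose 2.59-fold and Lamb1 fell by 0.45, while the abundant Lama5 changed by 0.07 (limma adjusted p = 0.542), Lamc1 by -0.03 (0.863) and Lamb2 by -0.21 (0.768). Of 29 extracellular matrix and collagen processing genes 1 rose, the prolyl hydroxylase P4ha2 (0.48), and 1 fell, Lamb1; adjusted over the list alone 4 rose and 5 fell, with Sparc at 0.16, Plod2 at -0.18 and Fn1 at -0.05 (not passed). The camera adjusted p was 0.10. The call of P4ha2 was lost without Calr KO replicate 1, Calr KO replicate 3, control replicate 2 or control replicate 3 (highest adjusted p 0.0843). Further genes outside the lists, chosen after their values were seen, were Hfe, an MHC class I-like regulator of iron uptake (0.92), Mdh1 (0.38), Pclaf (0.32) and Odc1 (0.21), which rose, and Kifc3 (-0.64), Gng2 (-0.64), Hace1 (-0.58), Nrp2 (-0.25) and Slc5a3 (-0.17), which fell. Of these Pclaf passed without each library in turn; highest adjusted p values of the others with 1 library left out lay between 0.0722 for Nrp2 and 0.174 for Kifc3.

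In the cell cycle list 0 of 26 passed over all genes or adjusted over the list alone, with Mki67 at -0.06, Top2a at 0.06 and a camera adjusted p of 0.067, which was 0.0079 without Calr KO replicate 2. The SREBP targets (0 of 27, Scd2 -0.03, Fasn -0.05, camera adjusted p = 0.135, and 0.0078 without Calr KO replicate 2), tRNA synthetases (0 of 20, Eprs 0.05, 0.315), NRF2 genes (0 of 17, Prdx1 -0.02, 0.979), p53 targets (0 of 14, Cdkn1a -0.14, 0.30) and apoptosis regulators (0 of 16, Mcl1 -0.02, 0.499) had no member past the test, also adjusted over the list alone. The same held for NF-kB targets (0 of 15, Ier3 -0.15, 0.753), chemokines and cytokines (0 of 19, Ccl2 -0.02, Csf1 -0.06, 0.441), integrins and adhesion (0 of 20, Flna -0.09, Itgb1 -0.08, 0.334) and calcineurin-NFAT genes (0 of 11, Mef2d -0.01, 0.0568), whose camera adjusted p was 0.031 without Calr KO replicate 3. Of 11 epithelial-mesenchymal markers 0 passed over all genes, and adjusted over the list alone 2 fell, S100a4 (-0.23) and Vim (-0.11), with a camera adjusted p of 0.583. Over all tested genes 37 passed in limma and 1172 had an unadjusted p under 0.05.

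Markers of other cell types gave no call. Of the macrophage markers 2 were tested, with Cd14 highest at 128 normalised counts, and of the lymphocyte markers 0. Of the endothelial markers 4 were tested (highest Egfl7, 174) and of the lung epithelial markers 1 (Hopx, 368). Of the fibroblast markers 6 were tested, with Col3a1 highest at 20994 and Pdgfra at a change of 0.04; 4 of these, Col3a1, Col1a2, Dcn and Lum, are also in the matrix list. Dcn had 31.9 against 15.5 (adjusted p = 0.312 over all genes) and passed adjusted over the list alone.

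The real split gave 37 genes and the highest of the other splits 2; for genes of at least 2-fold these were 5 and 1. In both cases 1 of the 10 splits of the 6 libraries, the real one, reached the count, and 10 splits are too few for a share under 0.05. Every other split also mixes Calr KO and control libraries within a group. Any real difference then adds to the spread within groups and lowers the count, so these splits cannot decide the question.

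The rise of 14 ER chaperones and disulfide isomerases was weighed against technical explanations. After the GC content and length correction the 14 called members had a median change of 0.504 (95% bootstrap interval 0.478 to 0.671). Their median was 0.513 before, which argues against such a trend for these 14 genes. They were chosen by their rise before correction, and the interval resamples genes, not wells. The lowest median under 3 other scalings was 0.503. Those scalings moved the median of all tested genes only from 0.00036 to between -0.0102 and -0.0015. That check could therefore hardly have lowered the rise. A general rise of abundant genes is also argued against, since the joint median of the 37 measured members, 0.195, lay above all 10000 level-matched lists (highest 0.06, share 0.0001, the smallest they can give). The knockout cannot be told apart from another difference between the transduced pools, because the design describes 1 pool per group.

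The lower Calr mRNA could come from a large deletion or silencing of its region. The median change of 28 tested genes within 500 kb was -0.036 (95% bootstrap interval -0.068 to -0.0017) with 0 called, which argues against it. Loss of transcript from edited alleles was not tested.

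Eif2s3y, a Y-linked translation factor gene noticed in the table, had 144 ± 31.8 against 62.4 ± 6.78 (log2 change 1.18, 95% interval 0.74 to 1.61, limma adjusted p = 0.057, not passed). It passed without Calr KO replicate 3 (adjusted p = 0.030, against up to 0.221 with another library left out), with a mean of at least 1 or no filter (0.048 each) and with a robust prior (0.047). Loss of the Y chromosome in part of the control cells could give such a value. Ddx3y, Uty and Kdm5d changed by 0.36, 0.38 and 0.02, with a median of 0.355, below the interval of Eif2s3y. The upper 95% bound of their mean, 0.561, also lay below it, but that bound takes the errors of these genes as independent. The 95% intervals of Ddx3y and Kdm5d, with upper bounds of 0.70 and 0.71, lay below that of Eif2s3y. The 95% interval of Uty, -0.15 to 0.90, overlaps that of Eif2s3y, so such a loss is not excluded. Reads shared with the X-linked copy Eif2s3x cannot be told apart, since the difference of Eif2s3x was -354.5 normalised counts (95% interval -831 to 122) and the gain of Eif2s3y, 81.7, lies within that spread.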
